A study of Homo sapiens with 6 samples.

How the data were processed

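RNA from 12Z cells was sequenced in 6 libraries, 3 from cells given frankincense extract (70 ug/mL in DMSO, 12 h) and 3 from cells given DMSO. Per the labels' protocols, cells grew in medium with 10% charcoal-stripped serum, total RNA was column-purified, and 1.5 ug of it went into a TruSeq RNA library kit. The samples are described as mRNA sequencing, and neither a poly(A) selection step nor a kit that keeps strand is stated, so antisense and overlapping genes cannot be separated.

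The deposited files hold 1 value per gene and library in each unit. Per the submitters' processing notes, STAR, RSEM 1.3.1 and GRCh38 were used; the STAR version, the annotation and the read filters are not given in the sources used here. Per the file headers, the authors' expected counts are RSEM's estimated reads per gene, which need not be whole because reads that fit several genes are divided between them. The deposited TPM values are transcript abundances scaled to the same total in each library and the deposited FPKM values fragments per kilobase of gene length scaled to library depth, per the file headers. The same files give, per the file headers, the length and effective length of each gene as a mean over its transcripts weighted by their abundance in that library. Because RSEM divides reads among similar genes, values of near-identical copies such as chaperone, histone, metallothionein, actin and tubulin genes are uncertain. Of 60616 gene identifiers, 60419 had a symbol in the gene name table, 178 more had a symbol from GENCODE 29, and 19 had none; 58385 had a position in GENCODE 29 (GRCh38), which gave the coordinates and gene types. FPKM served only to compare library sums.

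Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults, TMM factors, glmQLFit with robust estimation and the legacy fit, and glmQLFTest on the group term, two-sided, with Benjamini-Hochberg adjustment over the 16719 genes kept. Genes at adjusted p under 0.05 were called. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Means and SDs of TPM are over the 3 libraries of a group. Depth ranged from 22615150 to 27615196 expected counts. Where a group had 3 or fewer counts in total, the fold was computed against a floor of 3 counts over the group. The 6 libraries were compared for duplicates by a chi-square test of their counts: per degree of freedom it was 3.86 to 4.44 between vehicle libraries, 4.15 between frankincense replicates 1 and 2, and 13.98 and 12.13 between these and frankincense replicate 3, so each library was counted as a separate sample.

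The tests, the alternatives, the gene lists and the naming rule were set before the data were examined. Lists came from textbook knowledge and hold 913 distinct genes, 805 of them tested. They cover cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and PPAR targets, LXR targets, NRF2, ATF4, the unfolded protein response, heat shock, metallothioneins, aryl hydrocarbon receptor, nuclear receptor drug metabolism, p53, pro-apoptotic and anti-apoptotic genes, pyroptosis and necroptosis, G1/S, G2/M, histones, DNA repair, immediate early genes, MAPK feedback, MYC and ribosome biogenesis, ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, glycolysis and hypoxia, NF-kappaB cytokines, type I interferon, MHC class I, eicosanoids, steroid receptors, glucocorticoid targets, integrins, extracellular matrix, metalloproteinases, epithelial-mesenchymal transition, TGF-beta, YAP and TEAD, WNT and NOTCH, angiogenesis, autophagy and lysosome, ferroptosis and iron, proteasome, cytoskeleton, and markers of epithelial, stromal, smooth muscle, endothelial, immune and mesothelial cells. Lists with 5 or more tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, on ranks, and with fry; adjustment was over the 47 such lists.

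Named genes are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in the higher group, a proper symbol and groups that do not overlap; for each list called by camera, the 4 called members with the smallest adjusted p in its direction and the 1 against it; for each list called by fry's mixed test alone, the 1 riser and the 1 faller with the smallest adjusted p; and 20 genes named whatever their result. The closing section also names the 10 called genes outside every list with the smallest adjusted p, and genes that later tests needed, which were chosen after their values were seen. A few genes that this rule selects are not reported here.

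Alternatives were median-of-ratios, upper-quartile and library size scaling, DESeq2 1.42.0 with and without its own filtering, limma-voom, limma with trend on log2(TPM + 1), other edgeR settings, no filter or at least 5 CPM in 3 libraries, leaving out mitochondrial or the 20 most abundant genes, a trend on gene length removed with a loess span of 0.5, the replicate number as a block, adjusted p under 0.01, glmTreat at a log2 change of 0.5, and each library left out in turn. A trend on GC content (known for 98.8% of tested genes) and TPM rescaled without mitochondrial genes were added after the data were seen. The code was tested on data simulated for frankincense against vehicle over 16442 genes with 200 changed: 60 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold were called, with 6 calls among 16222 unchanged genes. A planted list was called by camera and 0 of 100 random lists were. Genes were simulated independently of each other, so these counts test the code and do not give the rate of false calls in these data. A planted length trend that gave 6526 calls in a separate simulation gave 0 once removed.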

Results

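The series measured mRNA by sequencing in 12Z cells, an immortalized line of human endometriotic epithelial-like cells that is used as a model of endometriosis, the growth of endometrium-like tissue outside the uterus. Cells received frankincense extract, a preparation of the resin of Boswellia trees, at 70 ug/mL in DMSO for 12 h, or DMSO alone as the vehicle. Each group had 3 libraries, each made from 1.5 ug of total RNA. The libraries held 22615150 to 27615196 expected counts over genes, with 23466 to 24391 genes above 0. At this depth 3 counts in a single library corresponded to 0.109 to 0.133 CPM, a limit that covers counting error only. Bounds on folds use a floor of 3 counts over a whole group, which is a lower level. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

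Most expressed genes differed in RNA level between extract and vehicle. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, was 14.6-fold higher, and DDIT3, the stress-induced transcription factor CHOP, was 5.67-fold higher. Genes of cholesterol synthesis, of the unfolded protein response, of the ATF4 pathway and of ribosome assembly were higher. Most tested genes in the lists of mitosis, type I interferon response, extracellular matrix, and tubulins and actins were lower, as were the mRNAs encoded by the mitochondrial genome, while both mitochondrial rRNAs were higher. These lists were called by camera at a preset correlation between genes, and 0 lists were called with an estimated correlation. Of 16719 genes tested, 10509 (62.9%) were called at adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5332 higher and 5177 lower after treatment. Changes of at least 2-fold were seen for 859 called genes that were higher and 1189 that were lower, and changes of at least 4-fold for 134 and 217. The other 80.5% of the calls were changes under 2-fold, with a median absolute log2 change of 0.54 over all called genes.

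Replicates were close together, with a biological coefficient of variation of 6.42%, and 67.5% of the tested genes had groups that did not overlap, where chance gives 10% for 3 libraries against 3. The leading principal component held 74.2% of the variance and separated the groups. The next held 7.99% and set frankincense replicate 3, at 27.6, apart from frankincense replicates 1 and 2, at -7.99 and -19.95. In that library the deviation from the mean of the other treated libraries rose with gene length (Spearman's rho of 0.30 across genes, which are not independent replicates). Without it, 11031 genes were called. When TPM values were tested in place of counts, 74.8% of the calls were higher, against 50.7% in the count test; the TPM scale moved the median log2 change of all tested genes by 0.20, and changes are given here relative to the count scaling, under which that median was -0.0016.

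Rises and falls were ranked among called genes with a mean of at least 5 CPM in the higher group, a proper symbol and groups that do not overlap. In that ranking the largest rises were those of HSPA6, an inducible cytosolic HSP70 chaperone, and of BHLHA15, a transcription factor of secretory cells. HSPA6 (ENSG00000173110, GRCh38 chromosome 1, 161524540 to 161526910) went from 0.0367 ± 0.047 to 4.25 ± 0.40 TPM (SD, n = 3), a log2 fold change of 6.52 ± 0.35 (SE). Its near-identical copy HSPA7 makes the value uncertain. BHLHA15 (ENSG00000180535, chromosome 7, 98211427 to 98212979) went from 0.133 ± 0.023 to 11.2 ± 1.26 TPM, a log2 fold change of 6.49 ± 0.17. BEX2, a brain-expressed gene on the X chromosome, rose 39.0-fold, KLHDC7B, a kelch-domain gene, 19.1-fold, and KRT34, a hair keratin, 17.5-fold. IL1RL1, the receptor of interleukin-33, rose 14.6-fold in the count test. Its TPM went from 0.933 ± 0.040 to 19.1 ± 1.59, a larger ratio than the count test gave. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) reached 866 ± 7.77 TPM from 49.9 ± 0.98, a log2 fold change of 3.86 ± 0.066 with an adjusted p of 4.2e-14 in edgeR. The remaining gene among the 8 largest rises was MT-RNR1, the small mitochondrial rRNA, at a log2 fold change of 4.02 ± 0.080.

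SUCNR1, the succinate receptor, fell the most among the genes ranked in this way, by 5.09 ± 0.22 on the log2 scale. It went from 3.46 ± 0.47 to 0.12 ± 0.060 TPM (ENSG00000198829, chromosome 3, 151873643 to 151884619). STC1, which encodes the secreted hormone stanniocalcin 1, was 31.4-fold lower (ENSG00000159167, chromosome 8, 23841915 to 23854807). METTL7A, a lipid-droplet methyltransferase-like gene, was 21.8-fold lower and the tetraspanin TSPAN8 18.1-fold lower. CCL2, the monocyte chemokine MCP-1, went from 50.6 ± 3.41 to 4.70 ± 0.95 TPM, 12.8-fold lower (ENSG00000108691, chromosome 17, 34255218 to 34257203). TRIL, a cofactor of toll-like receptor signalling, was 13.5-fold lower, and VIT, which encodes the matrix protein vitrin, 11.4-fold lower. The antisense RNA PKD1L1-AS1 was 13.6-fold lower, but the library kit is not stated to keep strand, so its reads cannot be told apart from those of overlapping genes.

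**Figure D1:**
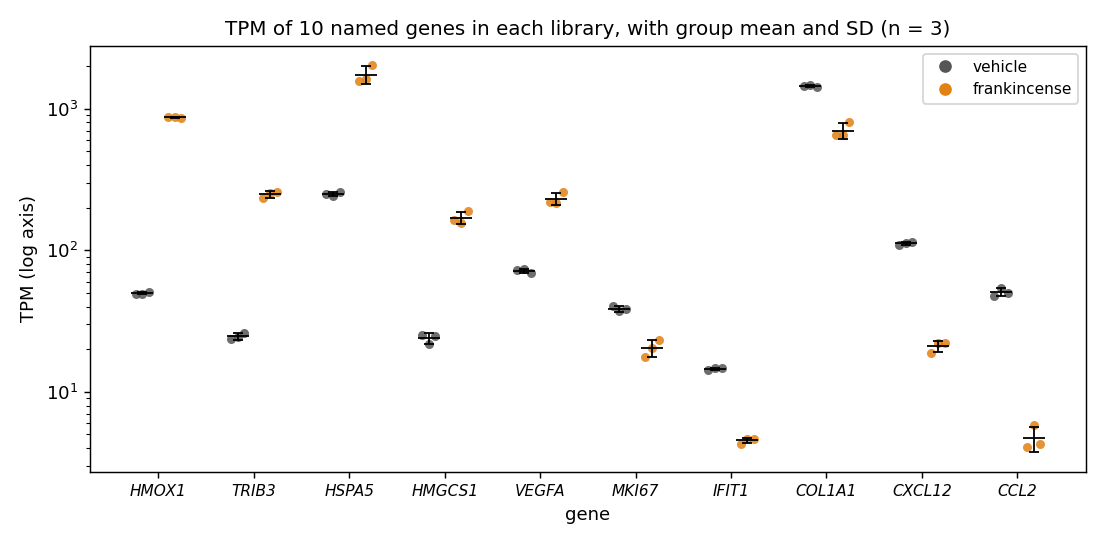
TPM on a log axis of 10 named genes in each of the 3 vehicle and 3 frankincense libraries; points are libraries, bars the group mean and SD. For each gene shown the 3 treated libraries lie on the same side of the 3 vehicle libraries, as for HMOX1, with means of 866 and 49.9 TPM.

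Gene groups were read from 50 lists fixed before the data were examined, 47 of which had 5 or more tested members. Limma's camera compares a list with all other genes. At a preset correlation of 0.01 between genes it called 21 lists, 7 higher and 14 lower. It called 0 when the correlation was estimated from the 6 libraries. The estimate was below 0.01 for the called lists of ATF4 (0.00038), LXR targets (0.0048), heat shock (-0.012), MYC targets (-0.018) and histones (-0.019). A larger correlation therefore cannot account for the loss of these lists, and the preset and estimated settings must differ in more than the correlation. For the other called lists the estimate was above 0.01. How much of their loss came from that correlation cannot be told from these values. Fry, a self-contained test that asks whether the members of a list change and does not compare them with other genes, called 41 lists in a direction and 47 in either direction. Members counted as higher or lower are those called over all genes tested, and the counts adjusted over the list alone were equal except where given.

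Endoplasmic reticulum and amino acid stress genes rose together. All 20 tested members of the unfolded protein response list were higher, with a median log2 change of 1.35 (camera adjusted p = 1.6e-10; adjusted p = 0.267 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 2.56 ± 0.073 to 1737 ± 248 TPM, HERPUD1, a degradation factor of that compartment, by 1.66 ± 0.052, and the chaperone cofactors MANF and SDF2L1 by 2.01 ± 0.064 and 1.95 ± 0.065. In the ATF4 and integrated stress response list 25 of 29 members were higher and 0 lower, with a median of 1.24 (camera adjusted p = 7.5e-11; adjusted p = 0.0669 with an estimated correlation). Examples were TRIB3, a pseudokinase, at 3.09 ± 0.062, GDF15, a stress-induced cytokine, at 3.11 ± 0.069, SLC3A2, the heavy chain of amino acid transporters, at 2.93 ± 0.069, and PPP1R15A, a phosphatase subunit that acts on eIF2-alpha, at 2.51 ± 0.061. DDIT3 rose by 2.50 ± 0.076, from 50.2 ± 3.46 to 340 ± 11.7 TPM.

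HSPA6 was not in the heat shock list. Of 19 tested members of the heat shock list, 11 were higher and 3 lower (12 and 3 adjusted over the list alone, 14 and 2 on the TPM scale), with a median of 0.34 (camera adjusted p = 0.0225; adjusted p = 0.202 with an estimated correlation). CHORDC1 and HSPH1, both cochaperones, rose by 1.19 ± 0.057 and 0.82 ± 0.056, HSPA4L by 0.80 ± 0.073, and HSPA1A by 0.61 ± 0.055, the latter being uncertain because HSPA1B is nearly identical. HSPE1, the mitochondrial cochaperonin, went the other way at -0.73 ± 0.080. Metallothioneins and other metal-response genes were higher in 7 of 7, with a median of 1.65 (camera adjusted p = 0.00104; adjusted p = 0.202 with an estimated correlation). MT1F rose by 3.02 ± 0.16, the zinc exporter SLC30A1 by 1.46 ± 0.10 and MT1E by 1.17 ± 0.12. MT1G had 0 counts in all vehicle libraries and 59 in the treated ones, at least 19.8-fold higher against a floor of 3 counts over the group, and the median of the list stayed at 1.65 with this bound. Reads of this family may be shared between its similar copies.

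Sterol genes were regulated in opposite directions by list. In the cholesterol synthesis and uptake list 22 of 24 members were higher and 1 lower, with a median of 1.18 (camera adjusted p = 8.1e-10; adjusted p = 0.202 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose by 2.52 ± 0.057 from 23.9 ± 1.99 to 169 ± 17.2 TPM. INSIG1, a sterol-sensing regulator, rose by 2.02 ± 0.052, FDFT1, squalene synthase, by 1.54 ± 0.051, and IDI1, an isoprenoid isomerase, by 1.85 ± 0.061. TM7SF2, a sterol reductase, was lower at -0.27 ± 0.095, a call lost when any of vehicle replicates 2 and 3 or frankincense replicates 2 and 3 was left out (adjusted p of 0.0714, 0.0535, 0.0527 and 0.0913). Among LXR targets and sterol efflux genes 6 of 7 were lower and 0 higher, and 3 and 1 on the TPM scale, with a median of -0.44 (camera adjusted p = 0.00822; adjusted p = 0.202 with an estimated correlation). MYLIP, a ubiquitin ligase that targets the LDL receptor, fell by 2.64 ± 0.11, the phosphodiesterase SMPDL3A by 0.86 ± 0.077, NR1H3, LXR-alpha itself, by 0.87 ± 0.089, and the efflux pump ABCA1 by 0.41 ± 0.067.

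Other lipid lists were not called by camera. Fatty acid synthesis genes were higher in 4 and lower in 3 of 11 (5 and 3 adjusted over the list alone, 7 and 1 on the TPM scale; camera adjusted p = 0.412), with FASN, fatty acid synthase, at 0.71 ± 0.055 and its regulator SREBF1 at -0.58 ± 0.058. Fatty acid oxidation and PPAR targets were higher in 3 and lower in 2 of 13, and in 6 and 1 on the TPM scale (camera adjusted p = 0.967), with PLIN2, a lipid droplet coat protein, at 1.16 ± 0.053 and ETFDH, an electron-transfer enzyme, at -0.54 ± 0.088. The median of that list was -0.054 and its mean 0.067, and the median was 0.021 with library size scaling.

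Antioxidant genes went both ways despite the rise of HMOX1. The NRF2 list had 11 members higher and 7 lower of 25, and 15 and 4 on the TPM scale (camera adjusted p = 0.337). PRDX1, a peroxiredoxin, fell by 1.39 ± 0.058 from 1179 ± 13.5 to 532 ± 9.33 TPM. Ferroptosis and iron handling genes were higher in 10 and lower in 6 of 17, and in 11 and 0 on the TPM scale, or 10 and 5 there without mitochondrial genes (camera adjusted p = 0.11), with NCOA4, the ferritin autophagy receptor, at -0.30 ± 0.051. Autophagy and lysosome genes were higher in 18 and lower in 7 of 28, and in 20 and 2 on the TPM scale (camera adjusted p = 0.0578, and 0.028 without frankincense replicate 1 and 0.0435 without frankincense replicate 3). SQSTM1, the autophagy receptor p62, rose by 1.42 ± 0.057 to 930 ± 80.2 TPM, and ULK1, an autophagy kinase, was at -0.52 ± 0.061. Proteasome subunits were higher in 5 and lower in 6 of 23, and in 15 and 3 on the TPM scale, or 6 and 5 there without mitochondrial genes (camera adjusted p = 0.838), with PSMD11 at 0.53 ± 0.047 and PSMA2 at -0.70 ± 0.055. Aryl hydrocarbon receptor targets were higher in 4 and lower in 0 of 7, and in 6 and 0 on the TPM scale (camera adjusted p = 0.148), with the amino acid transporter SLC7A5 at 1.24 ± 0.060. CYP1A1, the classical target of that receptor, was at 1.47 ± 0.56 (edgeR adjusted p = 0.0336) on a mean of 0.320 ± 0.017 TPM after treatment, and its call was lost when any library except vehicle replicate 3 was left out (adjusted p of 0.0551 to 0.0857). Nuclear receptor drug metabolism and transport genes were higher in 2 and lower in 2 of 7, and in 2 and 0 on the TPM scale (camera adjusted p = 0.881), with the carboxylesterase CES2 at 0.57 ± 0.076 and the cytochrome CYP3A5 at -0.48 ± 0.13.

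Ribosome assembly genes were higher and genes of the mitochondrial genome split by class. Of 24 MYC targets and ribosome biogenesis genes, 22 were higher and 1 lower, with a median of 0.71 (camera adjusted p = 4.1e-08; adjusted p = 0.0687 with an estimated correlation). SRM, spermidine synthase, rose by 1.23 ± 0.060, and the ribosome assembly factors RRP9, DKC1 and WDR43 by 1.25 ± 0.063, 0.86 ± 0.048 and 0.87 ± 0.055. FBL, the rRNA methyltransferase fibrillarin, was lower at -0.16 ± 0.055, a call lost without vehicle replicate 1 (adjusted p = 0.103) or vehicle replicate 3 (adjusted p = 0.0627), and its TPM-based change had the opposite sign. Cytosolic ribosomal protein genes were higher in 2 and lower in 9 of 33 (2 and 8 adjusted over the list alone; camera adjusted p = 0.306), from RPL10A at 0.24 ± 0.057 to RPL7A at -0.92 ± 0.072. On the TPM scale 16 were higher and 4 lower, and 6 and 8 when TPM was rescaled without mitochondrial genes, with a median of -0.029. Their median of -0.054 turned to 0.020 with library size scaling, and in frankincense replicate 3 they lay 0.29 below the mean of the other treated libraries on the log2 scale.

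All 13 mRNAs of the mitochondrial genome were lower, with a median of -1.42 (camera adjusted p = 4.7e-08; adjusted p = 0.419 with an estimated correlation). The largest falls were those of MT-ND6, at -2.84 ± 0.065, and of MT-CO2, a subunit of cytochrome oxidase, at -2.60 ± 0.076, from 37410 ± 463 to 7326 ± 432 TPM. MT-ND6 alone among these mRNAs lies on the minus strand of the reference. The kit is not stated to keep strand, so its reads cannot be told apart from those of transcripts of the other strand. MT-ND5 and MT-ND3, subunits of complex I, fell by 2.22 ± 0.073 and 1.99 ± 0.067. MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601) rose from 714 ± 53.4 to 12227 ± 440 CPM. These mRNAs made up 13.5% ± 0.34 of all counts in the vehicle libraries and 4.99% ± 0.39 in the treated ones, while both mitochondrial rRNAs made up 0.888% ± 0.016 and 5.16% ± 0.39 (SD, n = 3). For each of these shares the smallest p that an exact permutation test of 3 against 3 libraries allows is 0.1, and the groups did not overlap.

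**Figure D2:**
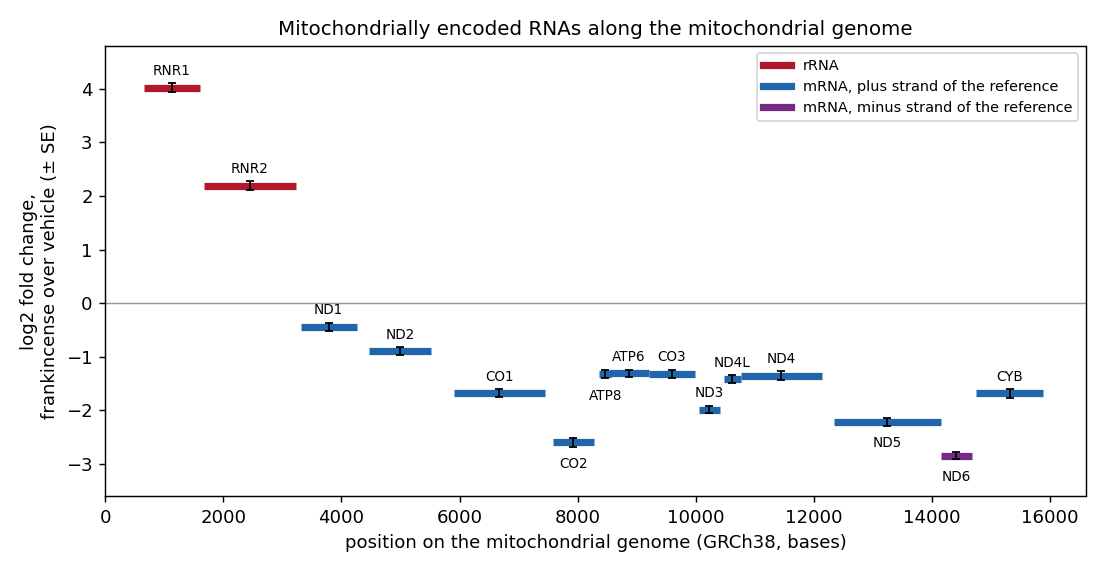
Log2 fold change (frankincense over vehicle, n = 3 libraries per group) of the mitochondrial rRNAs and mRNAs against their position in bases on the mitochondrial genome; horizontal bars span each gene and vertical bars are SE. Both rRNAs lie above 0 and the 13 mRNAs between -0.44 and -2.84.

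Nuclear-encoded oxidative phosphorylation genes were lower in 15 and higher in 1 of 25, with a median of -0.21 (camera adjusted p = 0.0246; adjusted p = 0.579 with an estimated correlation). The median turned to 0.044 on the TPM scale, with 9 lower and 9 higher, and was -0.14 with 11 lower and 2 higher when TPM was rescaled without mitochondrial genes. In frankincense replicate 3 these genes lay 0.18 below the mean of the other treated libraries. SDHA, a subunit of complex II, fell by 0.58 ± 0.050, NDUFB3 by 1.11 ± 0.093, COX7A2 by 0.64 ± 0.065 and ATP5F1A by 0.51 ± 0.065. SDHB was higher at 0.16 ± 0.065, a call lost when any library except frankincense replicate 3 was left out (adjusted p of 0.0622 to 0.213). Glycolysis and hypoxia response genes were lower in 20 and higher in 5 of 28, and in 13 and 6 on the TPM scale, with a median of -0.51 (camera adjusted p = 0.00153; adjusted p = 0.419 with an estimated correlation). LDHA, lactate dehydrogenase A, fell by 1.49 ± 0.064, ENO2, an enolase, by 1.02 ± 0.054, the hypoxia-induced gene NDRG1 by 1.34 ± 0.068 and PGAM1, a mutase of glycolysis, by 0.79 ± 0.055. Against the list, VEGFA, the main growth factor of blood vessels, rose by 1.47 ± 0.061 from 71.6 ± 2.60 to 230 ± 22.4 TPM.

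Most mitosis genes were lower. The G2/M and mitosis list had 34 of 36 members lower and 0 higher, with a median of -0.68 (camera adjusted p = 2.9e-11; adjusted p = 0.202 with an estimated correlation). KIF20A, a kinesin of cytokinesis, fell by 2.05 ± 0.056, the spindle gene ASPM by 1.19 ± 0.053, ANLN, an actin-binding protein of the cleavage furrow, by 1.15 ± 0.054, CENPF, a centromere protein, by 1.08 ± 0.055 and MKI67, the proliferation marker Ki-67, by 1.19 ± 0.065. G1/S and DNA replication genes were lower in 23 and higher in 5 of 35, with a median of -0.28 (camera adjusted p = 0.00594; adjusted p = 0.53 with an estimated correlation). On the TPM scale 9 were lower and 10 higher, with a median of -0.0055, and 16 and 4 without mitochondrial genes. RRM2, a subunit of ribonucleotide reductase, fell by 1.07 ± 0.060, the sliding clamp PCNA by 0.95 ± 0.059, UHRF1, a maintenance factor of DNA methylation, by 0.82 ± 0.052 and TK1, thymidine kinase, by 0.68 ± 0.050. CDC6, a licensing factor of replication origins, rose by 1.57 ± 0.055. Replication-dependent histone genes were lower in 8 of 9 (9 adjusted over the list alone), with a median of -2.25 (camera adjusted p = 8.3e-05; adjusted p = 0.171 with an estimated correlation). H2BC21, H2AC6, H2BC5 and H2BC12 fell by 2.25 ± 0.13, 1.98 ± 0.18, 2.30 ± 0.22 and 1.34 ± 0.14; most histone mRNAs lack a poly(A) tail, and similar copies can share reads.

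Genes of DNA damage responses were mixed. Of 25 p53 targets, 17 were higher and 3 lower, and 21 and 0 on the TPM scale, with a median of 0.33 (camera adjusted p = 0.000402; adjusted p = 0.202 with an estimated correlation), and 7 of the fixed members stand in other lists too. GADD45A, a growth arrest gene, rose by 3.20 ± 0.087, SESN2, a stress-induced regulator of mTORC1, by 1.78 ± 0.070, and TIGAR, a phosphatase of sugar metabolism, by 1.36 ± 0.092. CDKN1A, the cell cycle inhibitor p21, rose by 0.82 ± 0.062. POLH, a translesion DNA polymerase, was at -0.61 ± 0.063, with the opposite sign on the TPM scale. Homologous recombination and Fanconi genes were higher in 7 and lower in 4 of 16, and in 11 and 0 on the TPM scale (camera adjusted p = 0.357), with PALB2 at 0.73 ± 0.055 and FANCI at -0.23 ± 0.052, the latter also of opposite sign on the TPM scale. Pro-apoptotic genes were higher in 9 and lower in 7 of 23, and in 15 and 5 on the TPM scale, or 9 and 5 there without mitochondrial genes (camera adjusted p = 0.643), with CYCS, cytochrome c, at 1.11 ± 0.053 and TNFSF10, the death ligand TRAIL, at -2.41 ± 0.12. Anti-apoptotic genes were higher in 4 and lower in 5 of 11, and in 6 and 3 on the TPM scale (camera adjusted p = 0.967), with BAG1 at 0.90 ± 0.069, BCL2 at 1.09 ± 0.13 and TNFAIP3, the NF-kappaB inhibitor A20, at -1.01 ± 0.061. Pyroptosis and necroptosis genes were higher in 2 and lower in 5 of 10, and in 3 and 4 on the TPM scale (camera adjusted p = 0.337), with GSDME, a pore-forming gasdermin, at 0.76 ± 0.047 and the cytokine IL18 at -0.74 ± 0.076.

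Interferon-response genes were lower in 25 and higher in 1 of 28, and in 19 and 2 on the TPM scale, with a median of -0.87 (camera adjusted p = 4.1e-08; adjusted p = 0.202 with an estimated correlation). IFI44L, IFI44 and IFIT1, all induced by type I interferon, fell by 1.93 ± 0.062, 1.60 ± 0.058 and 1.92 ± 0.065, and OAS2, a sensor of double-stranded RNA, by 1.59 ± 0.070. IFIT5 rose by 0.45 ± 0.064. MHC class I antigen presentation genes were lower in 8 and higher in 2 of 14, and in 4 and 4 on the TPM scale, or 8 and 2 there without mitochondrial genes (camera adjusted p = 0.0543, and 0.0353 without frankincense replicate 3), with the peptide transporter gene TAP2 at 0.33 ± 0.067 and TAPBP, tapasin, at -0.96 ± 0.051. NF-kappaB cytokines and chemokines split, with 9 higher and 13 lower of 26, and 11 and 12 on the TPM scale (camera adjusted p = 0.286). CXCL2, a neutrophil chemokine, rose by 1.74 ± 0.062 while CXCL6, of the same family, fell by 2.90 ± 0.074. IL6 rose by 0.92 ± 0.12, and CXCL8, interleukin-8, was at -0.20 ± 0.053, with the opposite sign on the TPM scale. Eicosanoid synthesis and receptor genes were higher in 2 and lower in 6 of 14, and in 2 and 2 on the TPM scale (camera adjusted p = 0.337), with the prostaglandin E synthases PTGES2 at 0.69 ± 0.058 and PTGES at -0.51 ± 0.070. PTGS2, cyclooxygenase 2, was at -0.44 ± 0.18 (edgeR adjusted p = 0.0428), a call lost when any library except frankincense replicate 3 was left out (adjusted p of 0.0708 to 0.181). Frankincense replicates 1 and 2, at 0.86 and 0.90 TPM, lay below the vehicle libraries (1.13 to 1.28 TPM). Frankincense replicate 3, at 1.82 TPM, lay above them. ALOX5, the 5-lipoxygenase that has been described as a target of boswellic acids, had 2 counts in all 6 libraries together and was not tested.

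Immediate early genes were higher in 6 and lower in 12 of 22 (8 and 12 adjusted over the list alone, 8 and 10 on the TPM scale; camera adjusted p = 0.394), from ATF3, a stress-induced transcription factor, at 2.49 ± 0.091 to CCN2, connective tissue growth factor, at -0.98 ± 0.057 among those named. MAPK feedback genes were higher in 5 and lower in 7 of 15 (5 and 8 adjusted over the list alone, 6 and 2 on the TPM scale; camera adjusted p = 0.715), with the phosphatases DUSP5 at 0.76 ± 0.063 and DUSP6 at -0.80 ± 0.064. CCND1, cyclin D1, was at 1.0 ± 0.32 on a mean of 0.407 ± 0.040 TPM after treatment, and its call was lost without vehicle replicate 3 (adjusted p = 0.0649) or frankincense replicate 1 (adjusted p = 0.0521).

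Most matrix genes were lower, and so were most stromal and fibroblast markers, which share COL1A1 and COL3A1 with the matrix list. In the extracellular matrix list 20 of 27 members were lower and 1 higher, and 10 and 4 on the TPM scale, with a median of -0.39 (camera adjusted p = 9.5e-05; adjusted p = 0.555 with an estimated correlation). COL1A1 and COL1A2, the chains of type I collagen, fell by 1.36 ± 0.066 and 1.06 ± 0.072, COL3A1 by 1.43 ± 0.081 and the laminin chain LAMA5 by 0.88 ± 0.056, while LOX, a collagen crosslinking enzyme, rose by 0.23 ± 0.065. In frankincense replicate 3 the genes of this list lay 0.20 above the mean of the other treated libraries. TGF-beta and SMAD targets were lower in 13 and higher in 2 of 17 (13 and 3 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.00167; adjusted p = 0.202 with an estimated correlation). ID1 and ID2, inhibitors of DNA binding that respond to SMAD signalling, were at -2.48 ± 0.072 and -2.18 ± 0.11, and the inhibitory SMAD6 was at -2.09 ± 0.099. TGFB1 itself fell by 0.76 ± 0.055 and VIM, vimentin, by 0.30 ± 0.064.

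Cytoskeletal genes were lower in 17 and higher in 0 of 19, and in 13 and 1 on the TPM scale, with a median of -0.63 (camera adjusted p = 1e-05; adjusted p = 0.444 with an estimated correlation). The tubulins TUBA1A and TUBB3 fell by 0.98 ± 0.052 and 0.98 ± 0.071, and the actins ACTB and ACTG1 by 0.86 ± 0.069 and 0.74 ± 0.060, all from families with similar copies. Integrin and focal adhesion genes were lower in 14 and higher in 6 of 22, with a median of -0.37 (camera adjusted p = 0.0292, and 0.06 without frankincense replicate 1; adjusted p = 0.621 with an estimated correlation). On the TPM scale 7 were lower and 7 higher, and 10 and 4 without mitochondrial genes. ITGB8 fell by 2.02 ± 0.11, VCL, vinculin, by 0.85 ± 0.065, ITGB4 by 0.79 ± 0.078 and the actin crosslinker ACTN4 by 0.49 ± 0.053, while ITGB3 rose by 0.57 ± 0.092. Metalloproteinase and plasminogen genes were higher in 5 and lower in 6 of 12 (camera adjusted p = 0.598), with MMP1, interstitial collagenase, at 2.40 ± 0.18, MMP2, a gelatinase, at -0.65 ± 0.056 and TIMP2, a metalloproteinase inhibitor, at -0.83 ± 0.062. Epithelial-mesenchymal transition genes were higher in 5 and lower in 6 of 13, and in 7 and 4 on the TPM scale (camera adjusted p = 0.715), with ZEB2, a repressor of epithelial genes, at 0.59 ± 0.055. YAP and TEAD targets were higher in 6 and lower in 4 of 16 (7 and 4 adjusted over the list alone, 9 and 2 on the TPM scale; camera adjusted p = 0.348), with CCN1 at 1.47 ± 0.062. WNT and NOTCH targets were higher in 3 and lower in 5 of 11, and in 4 and 3 on the TPM scale (camera adjusted p = 0.643), with the ligand JAG1 at 0.94 ± 0.071 and the receptor NOTCH3 at -1.88 ± 0.069. Angiogenesis factors were higher in 6 and lower in 5 of 14 (6 and 6 adjusted over the list alone, 8 and 3 on the TPM scale; camera adjusted p = 0.967), with PDGFB at -0.99 ± 0.096.

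Steroid hormone receptor and steroidogenesis genes were higher in 3 and lower in 5 of 12, and in 3 and 3 on the TPM scale (camera adjusted p = 0.196), with HSD17B4 at 0.35 ± 0.052 and STAR, the cholesterol carrier of steroid synthesis, at -2.23 ± 0.19. The receptors were near the detection limit. ESR1, estrogen receptor alpha, went from 0.117 ± 0.040 to 0.33 ± 0.082 TPM (log2 fold change of 1.20 ± 0.31, edgeR adjusted p = 0.00362). ESR2, estrogen receptor beta, went from 0.18 ± 0.030 to 0.0833 ± 0.0058 TPM (-1.48 ± 0.38, adjusted p = 0.0032), and PGR, the progesterone receptor, was not called (-0.51 ± 0.27, adjusted p = 0.118, and 0.0294 without frankincense replicate 3). Glucocorticoid receptor targets were higher in 4 and lower in 5 of 11 (4 and 6 adjusted over the list alone, 4 and 4 on the TPM scale; camera adjusted p = 0.396), with TSC22D3, the leucine zipper gene GILZ, at 1.05 ± 0.071 and CRISPLD2 at -1.59 ± 0.084.

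Marker lists of cell types that a culture could hold gave these values. Endometrial stromal and fibroblast markers were lower in 9 and higher in 1 of 10, with a median of -1.39 (camera adjusted p = 0.00034; adjusted p = 0.312 with an estimated correlation). LUM and DCN, small proteoglycans of the matrix, fell by 1.98 ± 0.062 and 1.76 ± 0.066, and the surface antigen THY1 by 1.45 ± 0.055, while MME, the peptidase CD10, rose by 0.64 ± 0.056. LUM stood at a mean of 565 TPM in the vehicle libraries. Smooth muscle markers were lower in 7 of 7, and in 3 of 7 on the TPM scale, with a median of -0.88 (camera adjusted p = 0.00307; adjusted p = 0.267 with an estimated correlation), among them TAGLN, an actin-binding protein, at -0.88 ± 0.064, SYNPO2 at -2.60 ± 0.23, LMOD1 at -0.76 ± 0.12 and DES, desmin, at -1.29 ± 0.33. Epithelial markers were higher in 2 and lower in 6 of 9 (camera adjusted p = 0.148), with keratin KRT7 at 0.94 ± 0.19 and ELF3, an epithelial transcription factor, at -2.77 ± 0.17. Of the endothelial markers 1 was tested and it was lower, of the immune markers 4 were tested with 1 lower, and of the mesothelial markers 4 were tested with 2 lower.

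**Figure D3:**
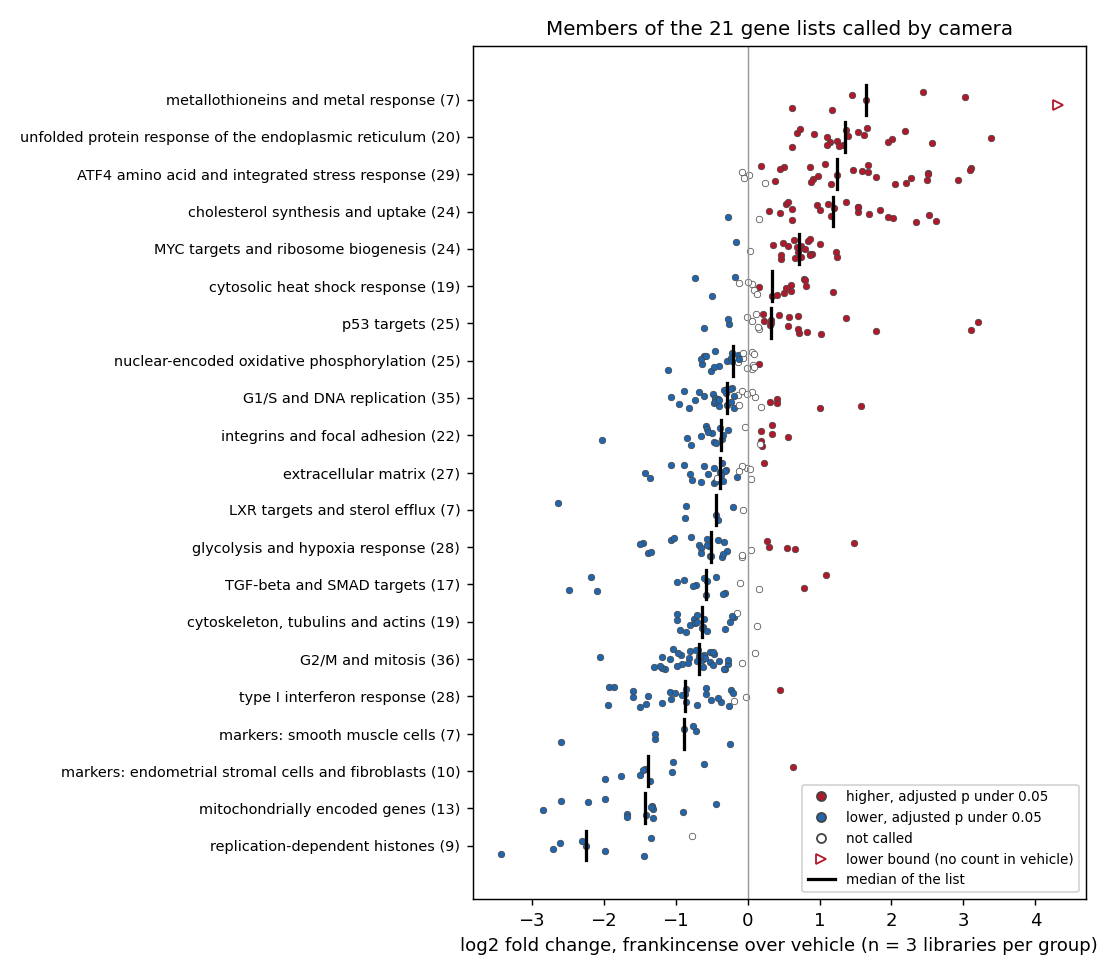
Log2 fold change (frankincense over vehicle, n = 3 libraries per group) of every tested member of the 21 lists called by camera at a preset correlation, with the number of tested members in brackets; filled points are called genes, open points are not, black bars are list medians and the triangle is a lower bound. Medians run from -2.25 for histones to 1.65 for metallothioneins, and that of oxidative phosphorylation, -0.21, changes sign on the TPM scale but not when TPM is rescaled without mitochondrial genes.

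List statistics differed in sign in a few cases. The median of the MAPK feedback list was -0.20 and its mean 0.0056, with camera downward. The angiogenesis list had a median of 0.082 and a mean of -0.10, with camera downward, and fatty acid oxidation had a mean above 0 with camera downward. Among uncalled lists, the medians of pyroptosis, immediate early, MAPK feedback, ribosomal protein, NF-kappaB, glucocorticoid, epithelial-mesenchymal, WNT and NOTCH, proteasome, fatty acid oxidation, immune and mesothelial genes changed sign on the TPM scale. The median of the anti-apoptotic list, 0.062, turned to -0.021 with the trend on GC content removed, and that of nuclear receptor drug metabolism, 0.34, to -0.0036 on the TPM scale without mitochondrial genes.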

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

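The tests of a lower mitochondrial share and of distance from the promoter, and that of gene length in frankincense replicate 3, were chosen after the result was seen, as were the GC trend alternative and the search for shifted transcript lengths; the others were set before their values were seen.

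Gene lengths, used only for trends in the comparison itself, held a difference between the groups: 168 of 9835 genes with at least 10 CPM had an abundance-weighted transcript length that moved by at least 10% with groups apart at adjusted p under 0.05 (limma on log2 length), 141 shorter and 27 longer after treatment. Each other split of the libraries gave 0, but these splits mix treated and vehicle libraries. The group difference then adds to the residual spread, so that 0 does not measure chance. Among the 168 genes, ERCC1, an excision repair gene, went from 1490 ± 13.1 to 1239 ± 1.0 bases, FKBP11 from 1130 ± 7.04 to 896 ± 8.55, and SRSF1, a splicing factor, from 2192 ± 13.9 to 2785 ± 4.13 (SD, n = 3). These examples were chosen after their values were seen. The number hung on single libraries: it was 0 without vehicle replicate 1, 41 without vehicle replicate 2, 18 without vehicle replicate 3, 66 without frankincense replicate 1, 47 without frankincense replicate 2 and 129 without frankincense replicate 3.

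Mitochondrial rRNA and mRNA moved apart, MT-RNR1 by 4.02 and MT-RNR2 by 2.20 upward and the 13 mRNAs downward. The share of mitochondrial reads did fall, from 14.4% ± 0.35 to 10.2% ± 0.78 of all counts (SD, n = 3). A fall common to all mitochondrial genes as the whole cause is excluded by the opposite signs, with a median of -1.42 for the mRNAs. All 417 nuclear copies of mitochondrial genes together changed by -7.9% of the MT-RNR1 change in CPM. RSEM had already divided shared reads between similar genes, so this does not exclude reads of copies credited to MT-RNR1. For a general carry-over of RNA without a poly(A) tail, the median over 15 RNAs, -1.45, cannot decide. Of these, 9 were histone mRNAs that can fall with replication. MT-RNR2, itself part of the pattern, alone rose by over 50% of MT-RNR1 on the log2 scale. The 5 other structural RNAs were at -1.18 to -1.62 with SE of 0.74 to 1.43, and were not called. Without vehicle replicate 2, at 224 CPM, structural RNA lay at 28.7 to 73.3 CPM in both groups. That argues against a carry-over as large as the 16.3-fold rise of MT-RNR1, but not against a smaller one. Distance from the heavy-strand promoter gave a rho of -0.69 over 14 genes (permutation p = 0.0076, Benjamini-Hochberg adjusted 0.015; Pearson's r of -0.76) but -0.51 over the 12 mRNAs alone (permutation p = 0.093), so it cannot be told apart from a difference between rRNA and mRNA. A candidate explanation that stays open is that the extract altered mitochondrial transcription or RNA turnover, or the length of poly(A) tails on mitochondrial RNA, which these libraries do not measure.

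The breadth of the calls was tested next. The 10 splits of 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 10509 genes, and the highest other gave 0. Every other split mixes treated and vehicle libraries, so its 0 does not measure calls by chance. A trend on gene length, on GC content, or a few abundant genes as the whole cause were each argued against, since 98.3%, 92.4% and 99.3% of the calls were kept in the same direction without them. An effect of the extract, the difference that the design names, stays open. So does a difference between the groups in culture or library preparation, because the labels do not say that the replicates came from separate cultures.

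Frankincense replicate 3 stood apart, with a chi-square per degree of freedom of 13.98 and 12.13 against the other treated libraries, where these gave 4.15 between them. Gene length as the whole cause is argued against, since removing the length trend took away 25.8% of the excess variance. A weaker or stronger response to the extract is also argued against, with a rho of -0.045 across genes between its deviation from frankincense replicate 2 and the response of frankincense replicate 1. What stays open is a difference in RNA quality or library preparation, no measure of which is given in the sources used here; 95.4% of the calls were kept in the same direction without this library.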

How the results depend on the processing

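The GC trend and the TPM values rescaled without mitochondrial genes were chosen after the data were seen. Called genes numbered 8633 to 11031 over all refits, and 0 of the calls were called in the opposite direction except on the TPM scale (54, and 10 once rescaled). Limma on TPM gave 2491 lower genes and 1215 of at least 2-fold; rescaling gave 1071, with 57.7% of the calls higher and a median change of 0.054 in place of 0.20, so that part of the shift came from the smaller mitochondrial share of TPM (26.9% ± 0.26 to 16.9% ± 0.84). A filter of 5 CPM, which tests 12009 genes, gave 1041 genes of at least 2-fold, and glmTreat against 0.5 gave 3479, its bound being lower. Gene lists called were 0 with an estimated correlation and 41 with fry, which asks another question. On TPM the changes of POLH (0.068), FANCI (0.042), FBL (0.14) and CXCL8 (0.026) had the opposite sign, none past the threshold, and 0 of the 4 did once TPM was rescaled without mitochondrial genes. For POLH the gap to its count-based change was larger than the median shift of 0.20. The count test did not adjust for transcript lengths that differ between the groups, so count and TPM changes of such genes can differ. Leaving out each library gave 9377 to 11031 called, 4740 to 5690 higher, 4637 to 5341 lower, 2049 to 2190 of at least 2-fold, and 21 to 23 lists. Over 179 named genes and 4265 values under alternatives, 68 values fell below the threshold and 2 rose past it. DESeq2's missing adjusted p (9 genes, 9875 with its own filter) stayed missing.

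With the replicate number as a replicate block, 10591 genes were called, 5347 higher and 5244 lower, and 98.3% of the calls were kept; no list call changed. Numbers do not pair the samples by the labels. Same-numbered libraries correlated in their deviations at 0.05, 0.10 and 0.035, each the best match of its library, a hint from the data, not the design.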

Other observations

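The tests of snoRNA host genes, tRNA synthetases, XBP1 and IRE1 substrates were set before their values were seen, except that the bound on the XBP1 length was added after its value was seen; no test in this part was otherwise chosen after the result was seen.

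Among called genes outside every list, those with the smallest adjusted p included BHLHA15, MT-RNR1 and IL1RL1, already named among the largest rises. FICD, an enzyme that modifies the chaperone HSPA5, rose by 3.10 ± 0.082 from 2.88 ± 0.046 to 25.7 ± 3.46 TPM, and SEC11C, a subunit of the signal peptidase, by 2.51 ± 0.065. HKDC1, a hexokinase-like enzyme, rose by 3.37 ± 0.076. CXCL12, a chemokine of stromal cells, fell by 2.75 ± 0.056 from 112 ± 2.62 to 21.1 ± 1.98 TPM, the laminin receptor BCAM by 2.66 ± 0.060 and the focal adhesion protein TNS2 by 1.90 ± 0.051. Each had an edgeR adjusted p of 1.4e-12 or less.

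Long noncoding genes that host small nucleolar RNAs were tested as a group. Of 29 tested, 18 were higher and 7 lower (camera p = 0.0136 at the preset correlation, not adjusted). Their median log2 change of 0.32 lay at percentile 99.99 of 10000 random lists of other long noncoding genes matched on expression, whose median was -0.19. This is in line with a coordinated rise, and as such hosts are translated and then degraded by nonsense-mediated decay, a lower rate of translation may contribute; that was not tested.

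Cytosolic tRNA synthetase genes were higher in 17 and lower in 1 of 20, with a median of 0.74, and mitochondrial ones were higher in 9 and lower in 3 of 17, with a median of 0.20. The difference of 0.55 exceeded that of permuted memberships (permutation p = 0.0033, 2-sided over genes). Cytosolic synthetases are known targets of ATF4, so a shared regulator with the ATF4 list is a candidate explanation for the gap.

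Activity of IRE1, the sensor of the unfolded protein response that splices XBP1 and cuts other mRNAs, may have changed. The mean length of XBP1 transcripts fell by 150 bases, from 1873 ± 7.65 to 1723 ± 32.5 (exact permutation p = 0.1, the smallest that 3 against 3 allows). The intron that IRE1 removes has 26 bases, so the shift is larger than splicing alone can give and the length cannot tell spliced XBP1 from other isoforms. Of 6 transcripts known to be cut by IRE1, the median was -0.80, with BLOC1S1 at -0.99 ± 0.11, SCARA3 at -1.48 ± 0.059 and PDGFRB at -1.04 ± 0.064. SPARC, COL6A1 and HGSNAT were at -0.61 ± 0.067, -0.32 ± 0.058 and -0.30 ± 0.052. Matrix genes and stromal markers fell in general, so for SPARC, COL6A1 and PDGFRB a fall common to such genes remains open.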
